A study of Homo sapiens with 3 samples.

How the data were processed

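Binding of p53 to chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in VCaP, an established human prostate cancer cell line that carries the p53 mutation R248W. Each of 3 libraries formed a group of its own: luciferase shRNA (the control), a first ERG shRNA, and an ERG shRNA numbered 2 (ERG shRNA 2 below). Per the labels' protocols, several immunoprecipitations were pooled into each library, so a library counted as 1 sample. The antibody is named as DO-1 in the labels of the first pair of libraries and in the series' design text. The label of the ERG shRNA 2 library names no antibody.

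Per the submitters' processing notes, Bowtie2, Picard 2.14.0, bedtools and MACS2 were used with the human build hg19. The role of Bowtie2, Picard and bedtools is not given in the sources used here. Per the file headers, MACS 2.2.7.1 called narrow peaks in each library separately, against an input library, with a p cutoff of 0.001 and at most 1 tag kept per position. The headers gave 9258451 tags for the control, 4853617 for ERG shRNA and 52175068 for ERG shRNA 2. The input total was 14360465 tags in each of the 3 headers, but the header of ERG shRNA 2 names its input differently, so a shared input rests on the equal totals. The larger of each library and its input was scaled to the smaller, per the file headers, so the pileup of ERG shRNA 2 rose in steps below 1 tag. MACS extended tags to 148, 115 and 154 bp in control, ERG shRNA and ERG shRNA 2, and no peak was narrower than that length.

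The deposited pileup is a coverage signal at the summit, in extended tags. The deposited significance columns hold the −log10 of the p and of the q for each peak, and their names were damaged in the spreadsheets, so their order was taken from the MACS layout. The deposited fold enrichment is a ratio of pileup to local background, each with 1 added. These scores are the authors' own and served to describe, rank or filter peaks within 1 list. The p cutoff, not q, set which peaks were listed. A second sheet of each workbook held the same coordinates as the first.

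Peaks of different lists counted as shared when they overlapped by at least 1 bp. Each overlapped share has an exact Clopper-Pearson 95% interval, which covers counting error only. Each share was set beside the mean of 100 random placements of the other list, with widths and chromosomes kept, and, chosen after seeing the data, of 100 shifts of each peak by 10 to 50 kb. The strength of overlapped and other peaks was compared within a list by the median fold enrichment and by the probability that an overlapped peak had the higher fold. The shares were also given per decile of a list by fold. The background at each peak was recovered from its deposited pileup and fold and divided by the genome-wide background that MACS uses as its minimum. Windows of 1 Mb were taken from the chromosome starts. A window counted as dense with 30 or more control or ERG shRNA peaks, or 20 or more ERG shRNA 2 peaks. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The overlap rules were tested on 3 simulated lists made from the 17986 control peak widths with known overlaps, where 0 peaks were misassigned. The counts also equalled those of bedtools 2.31.1.

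With 1 library per group there is no replicate check, no p-value is given, and every interval, those of differences included, compares these libraries and not the conditions. The smallest pileup that the p cutoff could list at a given background was computed from the Poisson tail. Between lists, such limits were compared as pileup divided by background, without the added 1. Overlap rules, stricter lists, lists of equal length and main chromosomes only were planned as alternatives before the data were examined. Leaving out dense windows or dense segments was added afterwards. Named regions were fixed by rule beforehand: the 10 control peaks of highest fold with, and the 10 without, an ERG shRNA overlap. The rule also took the 5 highest control peaks found in both ERG shRNA lists, the 5 highest ERG shRNA peaks without a control overlap, and the 5 highest ERG shRNA 2 peaks. Other regions named were chosen after their values were seen. Coordinates are 1-based hg19 positions from the files. The gene table used covers GRCh38.p14, a different build, so no peak was assigned to a gene by position. The planned locations relative to genes, motif searches, fixed gene lists and named loci were not analysed here.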

Results

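The series asked where mutant p53 sat on chromatin in VCaP prostate cancer cells and whether that changed when ERG, an ETS family transcription factor, was knocked down. ChIP-seq for p53 was done once with luciferase shRNA as the control and once with each of 2 ERG shRNAs. Gene expression, and so the degree of ERG knockdown, was not analysed here. The control library held 9258451 tags, ERG shRNA 4853617 and ERG shRNA 2 52175068. Each header gave the same input total of 14360465 tags, under another input name for ERG shRNA 2.

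The control and ERG shRNA lists were of similar length, with 17986 and 17321 peaks, and the ERG shRNA 2 list held 433. The deepest library, with 5.64 times the control's tags, thus had the shortest list. The median peak was 162 bp wide in the control, 115 bp in ERG shRNA and 218 bp in ERG shRNA 2, and the median fold enrichment was 4.37, 4.18 and 3.15. In the control, 14346 peaks (79.8%, 95% interval 79.2 to 80.3) had a q of at most 0.05. In ERG shRNA 12582 peaks (72.6%, 72.0 to 73.3) did, and in ERG shRNA 2 36 peaks (8.31%, 5.89 to 11.3). At −log10 q of at least 5, the control held 1196 peaks, ERG shRNA 1037 and ERG shRNA 2 none. The highest fold in ERG shRNA 2 was 6.90, against 28.5 in the control and 191 in ERG shRNA. The genome-wide background was 0.51 tags in the control, 0.21 in ERG shRNA and 0.82 in ERG shRNA 2. With 1 added to each, folds of different lists are not on the same scale. The median −log10 p and −log10 q were 5.61 and 2.01 in the control and 5.58 and 1.77 in ERG shRNA. In ERG shRNA 2 the upper quartiles were 5.84 and 0.32. A similar p thus had a far weaker q in ERG shRNA 2, so its q shares are not on the scale of the others.

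Chromosome 9 carried the most control peaks per Mb, 11.1, followed by chromosome 5 with 8.34 and chromosome 8 with 8.22. Chromosome 16 carried the fewest, 2.17. In ERG shRNA chromosome 9 also led, with 8.82 peaks per Mb, and chromosome Y was lowest with 2.46. In ERG shRNA 2, chromosome X held 224 of the 433 peaks (51.7%), against 3.69% of control peaks and 5.24% of ERG shRNA peaks. Chromosome 8 held 48 further ERG shRNA 2 peaks (11.1%). Peaks on unplaced or alternative contigs numbered 72 in the control, 130 in ERG shRNA and 21 in ERG shRNA 2.

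**Figure D1:**
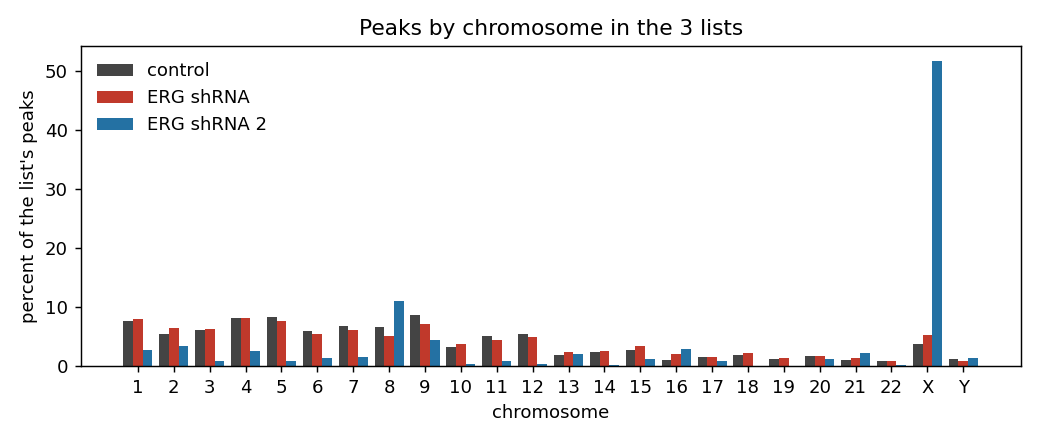
Share of each list's peaks on each chromosome, in percent of the list, for the control (grey), ERG shRNA (red) and ERG shRNA 2 (blue). Chromosome X holds 51.7% of the ERG shRNA 2 list, against 3.69% and 5.24% in the other lists.

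Part of the control and ERG shRNA peaks lay in a few dense windows. The densest was chromosome 9 at 42 to 43 Mb, with 169 control and 132 ERG shRNA peaks. Chromosome 5 at 69 to 70 Mb held 158 and 84, chromosome 9 at 70 to 71 Mb 93 and 76, and chromosome 1 at 148 to 149 Mb 86 and 79. In all, 46 windows with 30 or more peaks in either list held 2117 control peaks (11.8%, 11.3 to 12.3) and 1634 ERG shRNA peaks (9.43%, 9.002 to 9.88). Of these windows, 16 held 30 or more peaks in both lists, 20 in the control list alone and 10 in the ERG shRNA list alone. Chromosome 9 had 10 of them and chromosome 1 had 7.

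Some windows were filled in 1 list and sparse in the other. Chromosome X at 49 to 50 Mb held 43 ERG shRNA peaks against 4 control peaks, and chromosome 4 at 9 to 10 Mb held 32 against 5. Chromosome 16 at 32 to 33 Mb held 53 against 19, and chromosome 21 at 9 to 10 Mb held 33 against 9. Chromosome 9 at 14 to 15 Mb went the other way, with 3 ERG shRNA and 32 control peaks. Chromosome 7 at 80 to 81 Mb held 7 and 32. These windows were chosen after their values were seen.

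**Figure D2:**
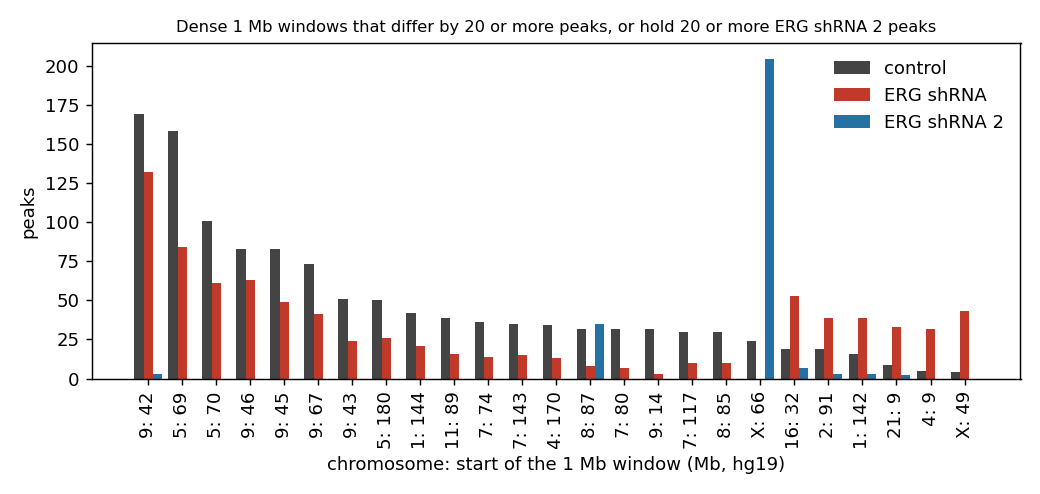
Peaks per 1 Mb window in the control (grey), ERG shRNA (red) and ERG shRNA 2 (blue), for dense windows where the control and ERG shRNA counts differ by 20 or more or ERG shRNA 2 holds 20 or more peaks. The window at 66 Mb on chromosome X holds 204 ERG shRNA 2 peaks, 24 control peaks and 0 ERG shRNA peaks.

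The comparison of control with ERG shRNA asked which control peaks were still called after ERG knockdown. Typical calls rested on few tags. The median pileup was 6 extended tags in the control (quartiles 5 to 7) and 5 in ERG shRNA (4 to 5). Nearly all of the strongest control sites had a counterpart. The peaks at chromosome 15, 55358319 to 55358522, and chromosome X, 122655650 to 122655855, had fold enrichments of 28.5 and 27.2 in the control list, and an ERG shRNA peak overlapped each. Most control peaks had none. Of the 17986 control peaks, 2427 (13.5%, 12.998 to 14.002) were overlapped by an ERG shRNA peak and 15559 were not. In the other direction, 2432 of the 17321 ERG shRNA peaks (14.04%, 13.5 to 14.6) were overlapped by a control peak. Random placement gave 0.203% and 0.210%, and shifts of 10 to 50 kb gave 0.635% and 0.659%. At shared sites the summits lay a median of 36 bp apart.

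The 10 strongest overlapped control peaks had folds of 20.5 to 28.5 on 9 chromosomes. Besides those above they included chromosome 6, 115239603 to 115239805 (fold 27.2), chromosome 13, 102294075 to 102294293 (26.1), and chromosome 3, 116226461 to 116226661 (23.5). Further ones were chromosome 5, 124907988 to 124908168 (22.6), chromosome 11, 85561297 to 85561510 (21.9), and chromosome 22, 29682898 to 29683190 (21.3). The last of them lay on chromosome 8, at 9424278 to 9424476 (20.6) and 79680712 to 79681146 (20.5).

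The 10 strongest control peaks without an ERG shRNA overlap had folds of 10.2 to 13.3. The highest was at chromosome 5, 117724290 to 117724538 (fold 13.3), followed by chromosome 4, 36459714 to 36459909 (12.8), and chromosome 4, 127984511 to 127984708 (11.4). Chromosome 10, 49220590 to 49220838, and chromosome 5, 102019946 to 102020154, had 11.3 each, and chromosome 2, 79604134 to 79604312, had 10.6. The others were chromosome 10, 47727259 to 47727531 (10.3), chromosome X, 56915742 to 56915984 (10.3), chromosome 6, 2070230 to 2070408 (10.2), and chromosome 7, 19728124 to 19728353 (10.2).

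The 5 strongest ERG shRNA peaks without a control overlap began with chromosome 15, 61108314 to 61108814 (fold 14.8). The other 4 had the same fold of 11.6: chromosome 11, 5246138 to 5247345, chromosome 7, 148529710 to 148529866, chromosome 8, 40472138 to 40472408, and chromosome X, 100694318 to 100694464. The chromosome 11 peak was 1208 bp wide.

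Overlapped control peaks were stronger than the others in the control list. Their median fold was 5.31, against 4.26, and an overlapped peak had the higher fold with a probability of 0.728. In the top decile by fold, 880 of 1799 control peaks (48.9%, 46.6 to 51.3) were overlapped, against 91 of 1799 (5.06%, 4.09 to 6.17) in the second-lowest decile and 143 of 1799 (7.95%, 6.74 to 9.30) in the lowest, so the share did not rise at every step. Of the 138 control peaks with a fold of at least 10, 128 (92.8%, 87.1 to 96.5) were overlapped. The ERG shRNA list had the same shape: 854 of 1732 peaks in its top decile (49.3%, 46.9 to 51.7) and 125 of the 137 with a fold of at least 10 (91.2%, 85.2 to 95.4) were overlapped by a control peak. Among peaks with a fold of at least 10, both lists held some at the places of highest ERG shRNA fold described below. No share was computed without them. The overlapped share depended on the strength asked for. Of the 1196 control peaks with −log10 q of at least 5, 711 (59.4%, 56.6 to 62.2) were overlapped by any ERG shRNA peak, and 635 of 1037 such ERG shRNA peaks (61.2%, 58.2 to 64.2) by any control peak. With both lists at that level the shares were 32.2% and 37.4%.

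**Figure D3:**
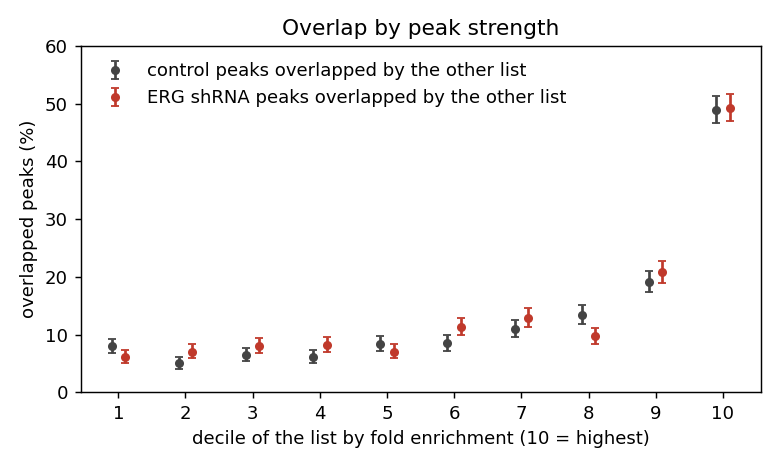
Percent of control peaks (grey) overlapped by an ERG shRNA peak, and of ERG shRNA peaks (red) overlapped by a control peak, per decile of each list by fold enrichment, with exact 95% intervals for counting error. The top deciles reach 48.9% and 49.3%, and each other decile stays at or below 20.8%.

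The highest values of the ERG shRNA list were at 3 places. Within 26.2 kb of chromosome 22, 29669684 to 29695859, it listed 11 separate peaks of 170 to 750 bp, with folds of 10.1 to 191. At chromosome 1 it listed 3 peaks from 166244849 to 166246891, of 115, 275 and 1446 bp with folds of 4.97, 28.2 and 147, and it listed one of 640 bp at chromosome 14, 36350195 to 36350834, with a fold of 88.2. The control list had peaks at the same 3 places with lower folds in its own list: 10 on chromosome 22, of 4.77 to 21.3, 2 on chromosome 1, of 10.6 and 12.8, and 2 on chromosome 14, of 6.14 and 7.30. The ERG shRNA 2 list had none there. On chromosome 22, the 5 ERG shRNA peaks from 29669684 to 29684820 had folds of 87.4 to 191, and the 6 from 29688447 to 29695859 folds of 10.1 to 27.4. With at most 1 tag kept per position and tags extended to 115 bp, the pileup is capped, and it reached 230 at the highest peak. The highest folds may therefore be understated. The list held 7 peaks over 80-fold, all at these 3 places, and the next highest peak had a fold of 29.1. Except for the rule-named chromosome 22 peak, the places were chosen after their values were seen.

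**Figure D4:**
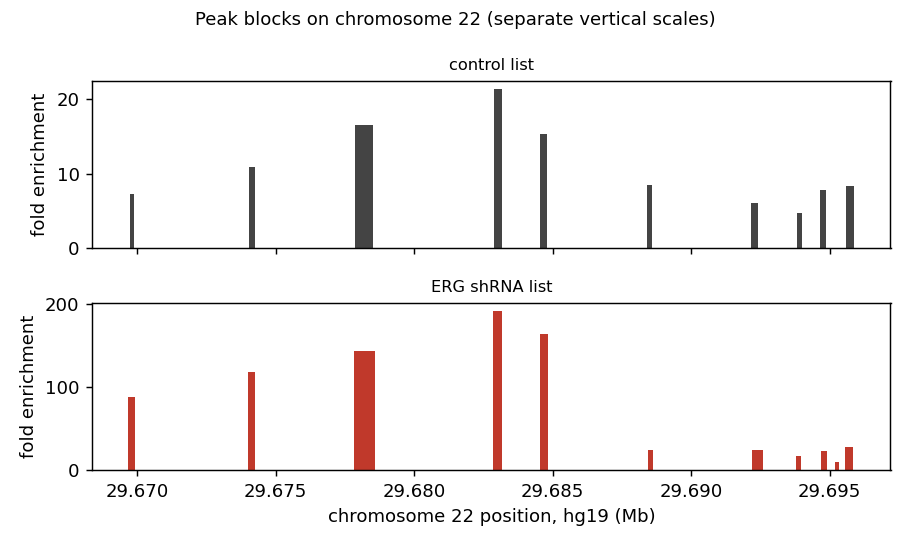
Peaks on chromosome 22 in the control (top) and ERG shRNA (bottom) lists, drawn to scale along the hg19 position in Mb, with bar height the authors' fold enrichment on separate vertical scales. The first 5 ERG shRNA peaks reach 87.4 to 191 and the other 6 stay at 27.4 or below.

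The comparison of control with ERG shRNA 2 asked the same of a second hairpin. Per the file headers this library's alignments carry another date-like tag, so a batch and the hairpin cannot be told apart. An ERG shRNA 2 peak overlapped 51 control peaks (0.284%, 0.211 to 0.373). In the other direction, 51 of 433 ERG shRNA 2 peaks (11.8%, 8.90 to 15.2) were overlapped by a control peak, against 0.289% after random placement and 1.48% after local shifts. Chromosome X, 66032202 to 66993196, held 204 ERG shRNA 2 peaks (47.1%, 42.3 to 51.9), 23 control peaks and 0 ERG shRNA peaks. The median background at the ERG shRNA 2 peaks there was 7.76 times the genome-wide value, and their median fold was 2.79. Of these ERG shRNA 2 peaks 4.41% had a q of at most 0.05, against 82.6% of the control peaks there, but q is not on the same scale in these lists. Chromosome 8, 87262487 to 87860535, held 35 ERG shRNA 2 peaks, 27 control peaks and 7 ERG shRNA peaks, and the median background at its ERG shRNA 2 peaks was 1.22 times the genome-wide value. Of its ERG shRNA 2 peaks 0% had a q of at most 0.05, against 66.7% of its control peaks, with the same limit. Without these segments, 46 of 194 ERG shRNA 2 peaks (23.7%, 17.9 to 30.3) were overlapped by a control peak. With the control list limited to its 433 strongest peaks, 10 of 433 (2.31%, 1.11 to 4.21) were.

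The 5 strongest ERG shRNA 2 peaks had folds of 6.38 to 6.90. They were at chromosome 12, 60411194 to 60411374, chromosome Y, 438016 to 438424, chromosome 2, 114857556 to 114857721, chromosome 16, 32827312 to 32827673, and chromosome 2, 83321486 to 83321650. Each overlapped an ERG shRNA peak, and 4 of the 5 a control peak, the exception being the one on chromosome 16.

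Between the hairpins, 52 of 433 ERG shRNA 2 peaks (12.0%, 9.10 to 15.4) were overlapped by an ERG shRNA peak, against 0.349% after random placement and 0.801% after local shifts. Without the dense segments on chromosomes X and 8 the share was 26.8% (20.7 to 33.6), and with the ERG shRNA list limited to its 433 strongest peaks it was 2.77% (1.44 to 4.79). Of the 51 control peaks found in ERG shRNA 2, 32 were also found in ERG shRNA. Independent lists would give 6.88, and draws of control peaks matched on decile of fold gave a mean of 12.1 and at most 23 in 10000 draws. Part of that excess may come from strength, since the top decile spanned folds of 5.97 to 28.5 and was not matched further. Part may come from the shared control list, and from the input if it was the same library. The 5 strongest control peaks found in both were chromosome 13, 102294075 to 102294293 (control fold 26.1), chromosome 8, 79680712 to 79681146 (20.5), and chromosome 4, 139803103 to 139803362 (19.2), then chromosome 2, 156303373 to 156303579 (11.9), and chromosome 2, 83321455 to 83321686 (11.4).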

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

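All tests here were chosen after the results were seen, and no difference between the hairpins was tested, since each had 1 library. In 25 windows of 1 Mb with 20 or more peaks in any list, the first ERG shRNA and ERG shRNA 2 differed from the control in opposite directions. In 23 of them ERG shRNA 2 was the lower one, which its short list gives almost anywhere, so 2 remained. At chromosome X, 66 to 67 Mb, ERG shRNA minus control was -24 peaks and ERG shRNA 2 minus control was 180. At chromosome 8, 87 to 88 Mb, the differences were -24 and 3.

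The ERG shRNA 2 peaks gathered on chromosome X rarely passed q, like their whole list. In the segment 4.41% of them had a q of at most 0.05, against 8.31% of all ERG shRNA 2 peaks. Their gathering may have a technical source, and the depth of the library stays open as one: 194 of its peaks lay outside the dense segments, but its tags were scaled to the smaller input, so more depth need not add peaks. The copy number of the segment, where it differed between library and input, remains open: the background at these peaks was 7.76 times the genome-wide value, but chromosome 8 at 86 to 87 Mb had 11.4 times at control peaks with 2 ERG shRNA 2 peaks, and the dense chromosome 8 segment had 1.22 times. Peaks covered 6.68% of the chromosome X segment. At the median background of these peaks, the smallest pileup that ERG shRNA 2 could list was 2.38 times the background. A smaller even difference in copy number would therefore leave the rest unlisted. ERG knockdown acting through both hairpins also stays open: ERG shRNA had 0 peaks there, but at its depth a pileup of at least 4.37 times the background was needed, above the median of 3.08 times at the ERG shRNA 2 peaks. An effect of the second hairpin alone, and of its batch, was not tested.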

How the results depend on the processing

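Of 61 alternatives, 22 left the value within its counting interval or 1.5 times the count, and 39 moved it. Shares and counts have no direction to reverse. The shares are given in the order control in ERG shRNA, ERG shRNA in control, control in ERG shRNA 2, ERG shRNA 2 in control, ERG shRNA 2 in ERG shRNA. A reciprocal overlap of 50% gave 9.66%, 10.0%, 0.189%, 7.85% and 7.62%. Peaks within 1000 bp gave 22.9%, 23.8%, 0.467%, 18.5% and 17.8%. Summits within 100 bp gave 11.4%, 11.9%, 0.195% and 8.08% for the first 4. With both lists at −log10 q of at least 5, the first pair was 32.2% and 37.4%. With only the first list at that level, the first 3 were 59.4%, 61.2% and 1.51%. ERG shRNA 2 had 0 peaks at that level, so its other shares gave no value. Lists of equal length moved the last 3, to 2.31%, 2.31% and 2.77%. Without dense windows, added after seeing the data, ERG shRNA in control was 13.5% and the last 3 were 0.208%, 23.6% and 27.1%. Without the dense segments, added likewise, the last 2 were 23.7% and 26.8%. Between control and ERG shRNA the shares ran from 9.66% to 61.2% over these alternatives.

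Peak counts for control, ERG shRNA and ERG shRNA 2 were 1196, 1037 and 0 at −log10 q of at least 5, and 4668, 3006 and 31 at a fold of at least 5. That fold needs a different pileup in each list, and q in ERG shRNA 2 is not on the scale of the other lists. ERG shRNA 2 held 194 peaks without the dense segments and 140 without dense windows. The probability that an overlapped control peak was the stronger was 0.750 by −log10 q, 0.651 for peaks within 1000 bp and 0.765 at a reciprocal overlap of 50%. The cause of these changes was not tested. The alternatives for locations, motifs and gene lists were not run. No paired analysis was possible because each group had 1 library and no test was made. Depth differed by 1.91 times between control and ERG shRNA, and peak lists alone cannot be thinned to a common depth.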

Other observations

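All tests here were chosen after the results were seen. Control peaks of −log10 q at least 5 formed 4 clusters of 4 or more within 10 kb of each other. Of these, 1 was the chromosome 22 place described above, where the ERG shRNA list had its 1 such cluster. The others were chromosome 19, 48434239 to 48449061, with 11 control and 12 ERG shRNA peaks, chromosome 19, 50617032 to 50634997, with 17 and 11, and chromosome 5, 70060227 to 70080538, with 13 and 7. ERG shRNA 2 listed 0 peaks in each. The median background at the control peaks was 3.76, 4.27 and 2.39 times the genome-wide value.

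The 7 ERG shRNA peaks over 80-fold, on chromosomes 22, 1 and 14, may come from spliced EWSR1 sequence, such as a plasmid or cDNA, in the libraries. EWSR1 encodes an RNA-binding protein that forms fusions with ETS factors in Ewing sarcoma, and in the gene table of GRCh38.p14 it is the 1 family of 2257 with numbered pseudogenes whose members lie on exactly these chromosomes. A copy gain of the chromosome 22 interval would fill it, but peaks covered 12.4% of it, and the stretches between peaks of 10.1-fold to 191-fold were not listed. After the peaks were seen, a single block was predicted at each pseudogene. Chromosome 1 had 3 ERG shRNA peaks instead. These covered 89.9% of their 2.04 kb, but coverage was not part of that prediction. Spliced EWSR1 sequence stays open, because no peak was assigned to a gene by position. ERG knockdown stays open too: the ERG shRNA 2 list held 0 peaks at the places, but also just 2 of the 10 strongest shared peaks. Apart from the chromosome 22 peak, itself at these places, those 10 had ERG shRNA folds of 14.9 to 29.1. Whether that list would hold peaks of over 80-fold can therefore not be told from them. The match to EWSR1 shown here is of chromosomes only, and it was searched for after the peaks were seen. Whether other ERG shRNA peaks without a control overlap come from carried-over sequence rather than p53 binding was not tested.

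Most control peaks had no ERG shRNA peak, and calls close to background are a candidate explanation: the overlapped share was 49.2 percentage points higher among control peaks with −log10 q of at least 5 than below it. Lower depth of ERG shRNA or a partial loss of binding would also spare strong peaks, so this gap cannot tell the explanations apart. If ERG knockdown removed sites, strong control peaks should be overlapped less often than strong ERG shRNA peaks. With partners of any strength the difference was -1.79 percentage points, with a 95% interval of -5.50 to 2.06 from drawing 1 Mb windows of both lists together, which compares these libraries only. With strong partners only it was -5.22 (-7.67 to -2.86), but 385 control and 388 ERG shRNA peaks were then overlapped, so this difference follows the lengths of the strong lists, 1196 and 1037. Loss of sites therefore stays open, as does the depth, 1.91 times higher in the control, and with 1 library per group they cannot be told apart.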
